A study of Mus musculus with 8 samples.

How the data were processed

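RNA of 8 pools of 2-cell mouse embryos, 4 wild-type and 4 DKO for Gadd45a and Gadd45b, was measured by RNA-seq. The labels give the C57BL/6N strain, females of 3 to 4 weeks, 23 to 35 embryos of 1 litter per pool and polyA RNA. Per the labels' protocols, cDNA was made with a SMART-Seq kit for very low input in 11 PCR cycles, libraries were made with the NuGEN Ovation Ultralow kit in 11 more PCR cycles, and all 8 libraries were sequenced together on 1 NextSeq flow cell as single reads of 85 cycles. Neither step as described marks individual molecules, so reads are not independent molecules, and intervals and floors cover counting error only.

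The deposited values are whole-number counts per gene, not normalized, in 1 table per library. Per the submitters' processing notes, the tools included bcl2fastq 2.19.1, FastQC 0.11.5, STAR 2.5.2b, featureCounts 1.5.1 of the Subread package and DESeq2 1.18.1, with the genome builds NCBIM37 and mm9. How featureCounts treated strand and reads that map to several places is not given in the sources used here. Genes whose sequence is repeated elsewhere can therefore lose reads or pass them to a copy, and reads of overlapping genes on opposite strands may not be told apart. The tables held 37310 Ensembl gene identifiers, of which 32620 matched a gene symbol and 4690 did not. The unmatched identifiers took 0.737% to 0.897% of a library's counts and were kept. Gene types, chromosomes, neighbourhoods, lengths and sequences came from GENCODE mouse release 21 on GRCm38, a later build than that of the counts, so no coordinates are printed and distances are those on GRCm38.

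Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, scaled with TMM and compared with the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 14970 genes, 13015 of them protein coding. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes (DKO minus wild-type) come from the same fit. All 8 libraries were used without covariates. Pools are separate litters. Pearson's r of log2 CPM across genes was 0.952 to 0.972 between pools of a genotype, and no pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 23.7). Scaling by RLE, upper quartile or library size alone moved the median log2 fold change of all genes by −0.01, 0.00229 and 0.05.

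A total of 35 gene lists with 1033 symbols was fixed before the data were examined. Of these symbols 37 were not matched in the tables. The others gave 985 list entries after repeats of a gene in a list were merged, and all 35 lists had at least 3 tested members. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with other genes. Camera with an estimated correlation and fry were run beside it; fry tests whether a list's genes move on balance one way or, in its mixed form, change in either direction, and does not compare the list with other genes. An adjusted p over a list alone covers that list's members only and is not adjusted over the 35 lists, so some lists can have a passing member by chance. Each list also had a score per pool, its mean log2 CPM, compared by an exact two-sided permutation test over the 70 assignments of pools, whose smallest p is 0.0286. Genes near the knocked-out loci, within 10 Mb and without the targets, were compared with genes on other chromosomes or beyond 20 Mb by Fisher's exact test. Intervals of shares are exact Clopper-Pearson intervals at 95%, and floors for 0 counts are 3 counts over the group.

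The genes named were set by a rule fixed before the data were examined: Gadd45a, Gadd45b and Gadd45g; genes past the threshold with a mean of at least 1 log2 CPM, no overlap between genotypes and a symbol that is not a placeholder, up to 10 with the highest and 10 with the lowest fold change and 5 more by smallest p in each direction; in each list up to 3 members past the threshold in each direction or, where none passed, the member with the smallest p; and Zscan4d, Zfp352, Dppa2, Dppa4, Tet3, Dnmt1, Cdkn1a, Mdm2 and Hspa1a. Other names were chosen after their values were seen, as stated beside them.

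Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings, no filter or a mean of at least 10 CPM, adjusted p thresholds of 0.01 and 0.1, a 2-fold minimum, protein-coding genes only, a replicate block, log2 embryos per pool as a covariate, other windows and each library left out in turn. The gene tests of edgeR and DESeq2 were run on simulated data, in 5 runs with 200 of 14970 genes changed. The changed genes were drawn from those with a mean of at least 1 log2 CPM, and genes were simulated without correlation. There edgeR recovered 58% of genes changed 2-fold and 91.2% of those changed 4-fold with a mean of 8.2 false calls. DESeq2 recovered 68.6% and 94.6% with 34.4 false calls. For lists, a shift of the maternal list by 0.3 on the log2 scale, simulated without correlation between genes, was called by camera in all of 5 separate runs. Fry, the permutation of scores, limma-voom and the test of neighbouring genes were not run on simulated data. DESeq2 gave no adjusted p for 6713 genes, which were left out of its counts.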

Results

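RNA was measured in pools of mouse embryos at the 2-cell stage, when the embryo replaces the RNA it inherited from the oocyte with transcripts of its own. The embryos were wild-type or carried a double knockout (DKO) of Gadd45a and Gadd45b, members of a family of small stress-inducible proteins linked to growth arrest, DNA repair and DNA demethylation. There were 4 pools per genotype, each of 23 to 35 embryos from 1 litter, collected 20 h after the vaginal plug from superovulated females of the same genotype as the embryos. The design therefore did not separate loss of the maternal from loss of the embryonic gene products. Each library held 21329736 to 23919114 counts, with 18433 to 20427 genes detected. Library totals did not differ detectably between the genotypes (n = 4 each, exact two-sided permutation test, p = 0.286). Pool size did not differ detectably, at 25.75 ± 2.99 wild-type and 28.25 ± 4.99 DKO embryos (SD, n = 4 each, exact two-sided permutation test, p = 0.543). The mitochondrial share of counts was 7.08% ± 0.945 in wild-type and 6.38% ± 0.351 in DKO (SD, n = 4 each). None of 7 such library measures passed an exact permutation test after Benjamini-Hochberg adjustment (adjusted p of 0.5 or more). With a smallest possible p of 0.0286, no single measure of the 7 could pass by itself, so this does not show that the libraries were balanced.

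The main comparison asked which transcripts differed between DKO and wild-type embryos. Gadd45b, a stress-response gene on chromosome 10 (ENSMUSG00000015312), was nearly absent in DKO, at 0.276 ± 0.244 CPM (counts relative to the scaled library total) against 45.3 ± 11.8 in wild-type (SD, n = 4 each). Gadd45a, a p53 target on chromosome 6 (ENSMUSG00000036390), was 2.12-fold lower, at 9.40 ± 1.69 against 20.0 ± 2.95 CPM (SD, n = 4 each), and lower in all 4 DKO pools than in any wild-type pool. The untargeted paralogue Gadd45g stood at 4.35 ± 1.71 CPM in DKO and 3.92 ± 2.32 in wild-type (SD, n = 4 each). Beyond Gadd45b, 3 genes differed in edgeR's quasi-likelihood test: mt-Nd3 and 1190007I07Rik fell and Gm10222 rose.

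Gadd45b counts were 910, 946, 1395 and 808 in the wild-type libraries and 4, 14, 1 and 6 in the DKO libraries. Its log2 fold change was −7.33 ± 0.42 (SE, edgeR adjusted p = 5.63e-07), so every library carried the Gadd45b level of its label. For Gadd45a the log2 fold change was −1.09 ± 0.22 (SE), with an edgeR adjusted p of 0.303 over all genes tested and 0.000324 adjusted over the list alone, the list being the GADD45 family fixed before the data were examined. DESeq2 gave Gadd45a an adjusted p of 0.00085, and the adjusted p ranged from 0.00085 to 0.614 over 23 alternative settings, of which 1 passed the threshold. Gadd45a counts were 237, 247, 163 and 201 in DKO. The counts cover whole genes and the deleted part of the Gadd45a allele is not given in the sources used here, so the remaining Gadd45a reads check nothing about the label. Gadd45g was not called (log2 fold change 0.15 ± 0.45, SE, edgeR adjusted p = 0.918), and its sign depended on the setting, between −0.15 and 0.43.

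mt-Nd3 (ENSMUSG00000064360), a mitochondrially encoded subunit of respiratory complex I, had 511 counts over the 4 wild-type libraries and 0 in DKO. With a floor of 3 counts over the DKO group it was at least 171-fold lower (edgeR adjusted p = 5.97e-05). Gm10222 (ENSMUSG00000067736), an unprocessed pseudogene on chromosome 1 whose sequence is identical to mt-Nd4l over 294 bases, rose from 0.134 ± 0.126 to 6.41 ± 0.889 CPM (SD, n = 4 each), a log2 fold change of 5.52 ± 0.51 (SE, edgeR adjusted p = 9.85e-05). 1190007I07Rik (ENSMUSG00000063320), a protein-coding gene on chromosome 10, fell from 8.04 ± 0.484 to 0.810 ± 0.395 CPM (SD, n = 4 each), a log2 fold change of −3.30 ± 0.35 (SE, edgeR adjusted p = 0.000556). All 3 genes separated the 4 DKO pools from the 4 wild-type pools. Gm10222 and 1190007I07Rik have placeholder symbols and were named after their values were seen. Reads of mt-Nd3 and Gm10222 are uncertain, because near-identical mitochondrial and nuclear sequences can share them, and 5 of the 13 mitochondrially encoded protein genes had 0 counts in every library. The other mitochondrially encoded protein genes with counts had a median log2 fold change of −0.19 (SD 0.10 over 7 genes).

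**Figure D1:**
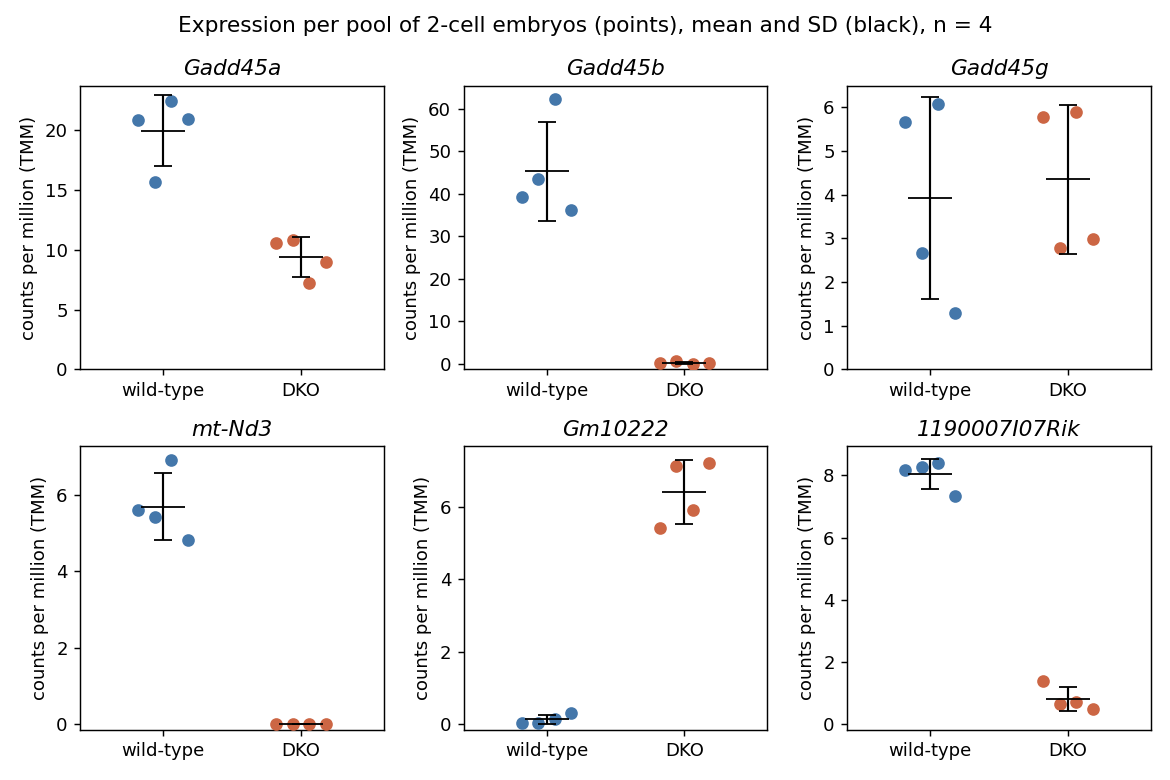
Each panel plots CPM (linear axis, TMM-scaled) of 1 gene for the 4 wild-type and 4 DKO pools, with points for pools and black bars for the mean and SD. Gadd45b and mt-Nd3 lie at or near 0 in every DKO pool, Gadd45a averages 9.40 against 20.0, Gadd45g overlaps between genotypes, Gm10222 averages 6.41 against 0.134 and 1190007I07Rik averages 0.810 against 8.04.

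Across the 14970 genes tested, 1 rose and 3 fell at an edgeR adjusted p under 0.05. An unadjusted p under 0.05 was reached by 1532 genes, where chance gives 748 on average, with a wider spread when genes are not independent. Of the 35 splits of the 8 libraries into groups of 4, 3, the real one included, gave at least 1532. The other splits had a median of 455.5 and a highest count of 2526. In 799 genes (5.34%) the DKO and wild-type values did not overlap, a share that chance puts at 2.86% on average. How far this share varies over other splits was not computed, and genes are not independent. DESeq2 called 49 genes, 30 higher and 19 lower, and these included the 4 genes called by edgeR. The common biological coefficient of variation was 0.313. In data simulated from these libraries edgeR recovered 58% of genes changed 2-fold and 91.2% of those changed 4-fold. There 200 genes were changed, all with a mean of at least 1 log2 CPM, and genes were not correlated. The real data gave 4 calls, so these shares need not hold for them.

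Maternal transcripts were called higher as a group in DKO embryos by camera with its preset correlation only. The correlation between genes estimated in the list was above the preset value, at 0.39, and fry did not call the list (fry adjusted p = 0.32). Of 53 measured oocyte-derived transcripts that are normally cleared after fertilization, 48 had a positive log2 fold change, with a median of 0.35 (camera adjusted p = 8.89e-08, adjusted p = 0.626 with an estimated correlation). By edgeR 14 members had a positive fold change at an unadjusted p under 0.05 and 0 passed after adjustment, over all genes or over the list alone, and DESeq2 and limma-voom called 0. Omt2b, an oocyte transcript and the member with the smallest p, stood at 3663 ± 955 CPM in DKO and 2193 ± 480 in wild-type (SD, n = 4 each), a log2 fold change of 0.74 ± 0.20 (SE, edgeR adjusted p = 0.469). Btg4, the adaptor that brings deadenylase to maternal RNA, had a log2 fold change of 0.79 ± 0.26 (SE, edgeR adjusted p = 0.469). Tcl1b3 and Omt2a, chosen after their values were seen, had log2 fold changes of 0.81 and 0.60. Among the 8 members of the subcortical maternal complex list, Nlrp4f was at 280 ± 82.7 against 148 ± 28.8 CPM (SD, n = 4 each), with a log2 fold change of 0.92 ± 0.21 (SE) and an edgeR adjusted p of 0.394 over all genes and 0.00439 adjusted over the list alone, 1 of the 8 passing there. DESeq2 called Nlrp4f (adjusted p = 0.0288), the only 1 of 23 alternative settings that did, with adjusted p up to 0.746. DKO replicate 1 stood apart from the other libraries, with a voom quality weight of 0.365, and without it the median of the maternal list was 0.15 (camera adjusted p = 5.5e-05).

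Genes of protein turnover, ribosome assembly, respiration and mitosis were called lower as groups by camera with its preset correlation only. The correlation between genes estimated in these lists was above the preset value, from 0.24 for the mitotic list to 0.85 for ribosomal proteins. With the estimated correlation camera called none of them, and neither did fry (fry adjusted p of 0.32 to 0.63). In the proteasome list 30 of 32 members had a negative log2 fold change, with a median of −0.29 (camera adjusted p = 1.05e-07, adjusted p = 0.626 with an estimated correlation). Psmc3, an ATPase subunit of the proteasome, was at 48.6 ± 5.28 against 70.3 ± 7.64 CPM (SD, n = 4 each), a log2 fold change of −0.53 ± 0.16 (SE, edgeR adjusted p = 0.469). Ribosome biogenesis had 61 of 68 members negative and a median of −0.22 (camera adjusted p = 2.89e-07, adjusted p = 0.626 with an estimated correlation), with Pes1, a factor of large-subunit assembly, at −0.61. The nuclear-encoded oxidative phosphorylation list had 65 of 75 members negative and a median of −0.19 (camera adjusted p = 3.67e-06, adjusted p = 0.626 with an estimated correlation). Its member with the smallest p was Atp5d, a subunit of ATP synthase that lies near Gadd45b, at −0.52. In the mitotic cell cycle list 27 of 31 members were negative, with a median of −0.22 (camera adjusted p = 4.76e-05, adjusted p = 0.626 with an estimated correlation), and the mitotic kinase Aurka was at −0.56 ± 0.19 (SE, edgeR adjusted p = 0.469). Ribosomal proteins had 71 of 76 members negative and a median of −0.14 (camera adjusted p = 0.000117, adjusted p = 0.719 with an estimated correlation).

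In these 5 lists edgeR called 0 members, over all genes or adjusted over the list alone, and DESeq2 and limma-voom called 0. At an unadjusted p under 0.05, 4 members of the proteasome list were lower, 5 of ribosome biogenesis, 10 of oxidative phosphorylation, 6 of the mitotic cell cycle and 1 of the ribosomal proteins. Without DKO replicate 1 the medians were −0.19 for the proteasome and −0.11 for ribosome biogenesis, and the ribosomal protein list was no longer called (median −0.04, camera adjusted p = 0.29). The ribosomal protein call was also lost without wild-type replicate 4 (median −0.02, camera adjusted p = 0.407), and its median was −0.25 without DKO replicate 2 and −0.22 without wild-type replicate 3. It was lost with limma-voom quality weights too (median −0.04, camera adjusted p = 0.115). Without both libraries numbered 1 the ribosomal protein call (adjusted p = 0.273) and the ribosome biogenesis call (median −0.07, adjusted p = 0.176) were lost, and the mitotic list, still called by camera, had a median of −0.10.

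**Figure D2:**
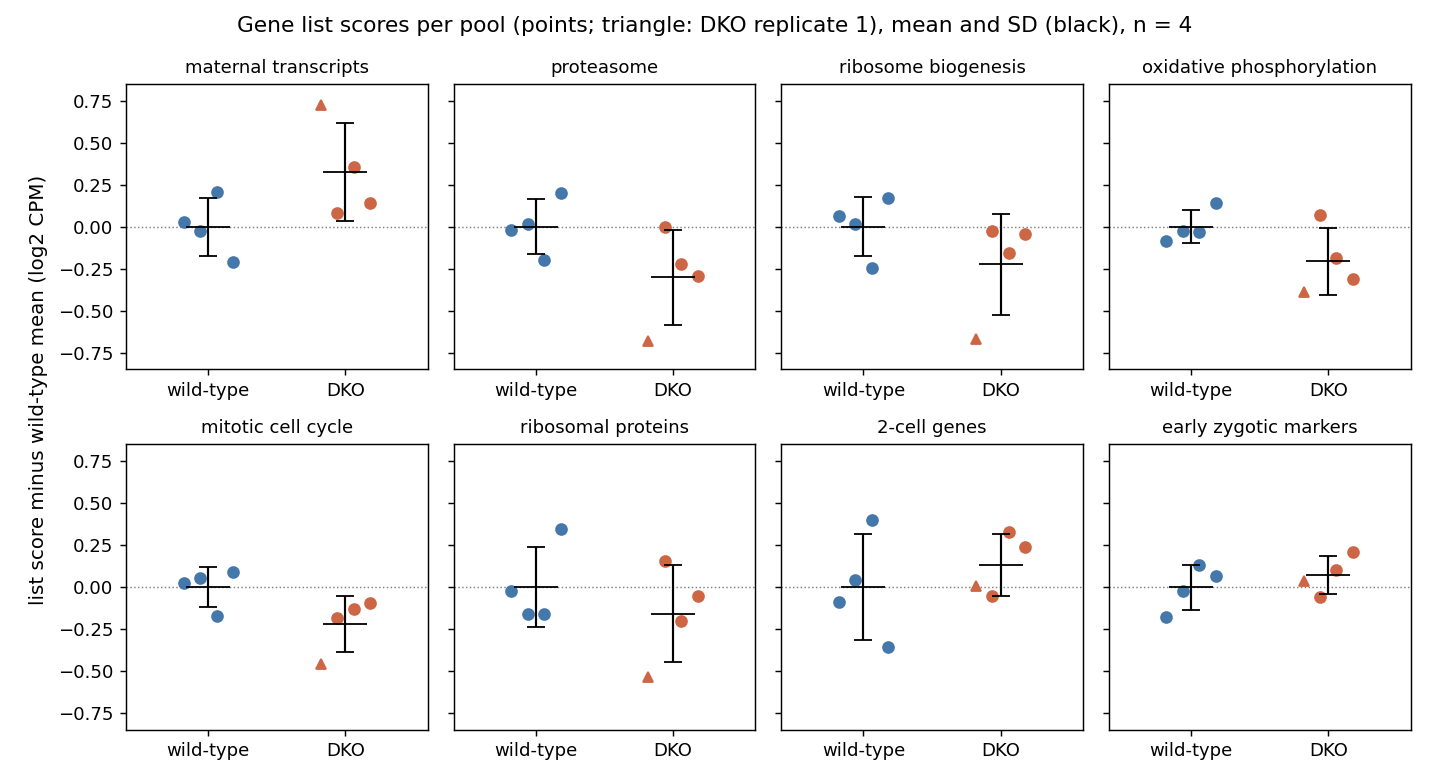
Each panel plots the mean log2 CPM of 1 gene list, minus its wild-type mean, for the 4 wild-type and 4 DKO pools, with points for pools, a triangle for DKO replicate 1 and black bars for the mean and SD. Maternal transcripts lie 0.33 above the wild-type mean in DKO and the proteasome list 0.30 below it, with DKO replicate 1 farthest out in both panels and the genotypes overlapping.

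Per pool, the maternal score was 6.94 ± 0.29 in DKO and 6.61 ± 0.17 in wild-type mean log2 CPM, and the proteasome score 7.27 ± 0.28 against 7.57 ± 0.16 (SD, n = 4 each). Exact two-sided permutation tests of such scores over the 35 lists called 0 lists, with a smallest adjusted p of 0.375, but 21 of the 35 would have to reach the smallest possible p for any to pass, so this 0 says nothing on single lists. In these tests 2 lists, the GADD45 family and the mitochondrial genome, reached the smallest unadjusted p possible with 4 pools against 4, 0.0286. The mitochondrial genome score differed by −0.74, and by −0.15 without mt-Nd3 (exact permutation p = 0.2), so that gene carried the separation. Camera called 9 lists with its preset correlation and 1 with an estimated correlation, and the rotation test fry called 1. In its mixed form, for change in either direction, fry called 3: the GADD45 family (fry adjusted p = 0.0149), the mitochondrial genome (2.67e-05) and the sperm list (0.0275). The list called by camera with an estimated correlation and by fry for 1 direction was the GADD45 family (camera adjusted p = 1.64e-17, adjusted p = 0.00354 with an estimated correlation), which holds the targeted genes and is not independent evidence. Its 4 members include a gene other than Gadd45a, Gadd45b and Gadd45g. Of the 4, 1 fell over all genes and 2 fell when adjusted over the list alone, Gadd45a and Gadd45b.

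The mitochondrial genome and sex-linked lists were also called lower. The mitochondrial genome list had a median of −0.17 over 10 members, unaffected by the bound used for mt-Nd3 as its lowest member (camera adjusted p = 9.63e-06, adjusted p = 0.626 with an estimated correlation). Leaving out mt-Nd3 gave a median of −0.15 and an unadjusted camera p of 0.0258 (0.37 with an estimated correlation), the call was lost at a mean of at least 10 CPM (median −0.11, camera adjusted p = 0.279), and the median was −0.09 without DKO replicate 3 and −0.11 without wild-type replicate 3. The sex-linked list of Y-chromosome genes and Xist had a median of −0.50 over 8 members (camera adjusted p = 0.0178, adjusted p = 0.626 with an estimated correlation). Y-linked genes and Xist go opposite ways with the mix of sexes in a pool; Xist itself had 194 counts in wild-type and 219 in DKO, and without it the median was −0.56 (unadjusted camera p = 0.00151, 0.097 with an estimated correlation). Uty, a Y-linked histone demethylase relative, had a log2 fold change of −0.66 ± 0.20 (SE), lower in all 4 DKO pools, with an edgeR adjusted p of 0.469 over all genes and 0.0395 adjusted over the list alone, where 2 members fell, the other being Usp9y. That list's call was lost without DKO replicate 1 (median −0.26, camera adjusted p = 0.0882), wild-type replicate 1 (adjusted p = 0.0844), wild-type replicate 2 (median −0.30, adjusted p = 0.0859) or both libraries numbered 1 (median −0.24, adjusted p = 0.247).

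Genes that mark the opening of the embryonic genome were not called as groups. The list of genes specific to the 2-cell stage was written with 43 symbols. Of these, 16, with Dux, Zscan4a, Tcstv1 and Tcstv3 among them, were not matched in the tables and not tested. The list as tested had 18 of 25 members positive and a median of 0.21 (camera adjusted p = 0.373). It was called higher in 1 of 20 alternative settings, without wild-type replicate 3 (median 0.30, camera adjusted p = 0.00809). With 1 library left out at a time, the median of that list ranged from 0.05 to 0.30. Zscan4d, a telomere regulator of this stage, was at 221 ± 57.4 against 206 ± 50.8 CPM (SD, n = 4 each, edgeR adjusted p = 0.867), and Zfp352 had a log2 fold change of 0.37. Tdpoz4 had the smallest p of the list, with a log2 fold change of −0.88 ± 0.26 (SE, edgeR adjusted p = 0.469, and 0.0751 adjusted over the list alone). Dppa2 and Dppa4, partner activators of 2-cell genes, had log2 fold changes of −0.57 and −0.39 (edgeR adjusted p = 0.48 and 0.489). Camera adjusted p was 0.992 for early zygotic markers, 0.396 for the Obox family, 0.404 for zygotic regulators and 0.601 for repressors of the 2-cell program.

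Genes of processes that GADD45 proteins take part in were not called as groups by camera in the main comparison either. Camera adjusted p was 0.745 for the DNA methylation machinery, 0.8 for base excision repair, 0.704 for p53 targets, 0.122 for DNA damage checkpoints, 0.577 for stress kinases, 0.404 for immediate early genes and 0.992 for apoptosis. In 1 of 20 alternative settings each, DNA damage checkpoints were called lower, with no filter on low counts (median −0.12, camera adjusted p = 0.0428), and immediate early genes, without both libraries numbered 1 (median −0.26, camera adjusted p = 0.0495). Tet3, the dioxygenase that oxidizes 5-methylcytosine in the zygote, was at 45.1 ± 26.3 against 29.3 ± 6.18 CPM (SD, n = 4 each, edgeR adjusted p = 0.489). DKO replicate 1 stood at 84.0 CPM, and DKO replicates 2, 3 and 4 at 25.8, 34.7 and 35.7. Over the alternative settings the log2 fold change of Tet3 ranged from 0.12 to 0.82. Dnmt1, the maintenance methyltransferase, and the p53 targets Cdkn1a and Mdm2 had log2 fold changes of 0.05, −0.13 and −0.01 (edgeR adjusted p = 0.942, 0.797 and 0.983). Zfp36, which destabilizes AU-rich RNA, was at 8.70 ± 1.27 against 15.7 ± 2.53 CPM (SD, n = 4 each), lower in all 4 DKO pools, with an edgeR adjusted p of 0.453 over all genes and 0.0312 adjusted over the list alone, where 1 of 21 immediate early genes passed. DESeq2 called Zfp36 (adjusted p = 0.0335), the only 1 of 23 alternative settings that did, with adjusted p up to 0.78. The base excision repair list had a median of −0.03 while its mean score differed by 0.02, and the apoptosis list had a median of 0.02 with a camera direction of lower.

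The remaining lists were not called by camera in the main comparison. Camera adjusted p was 0.0712 for DNA replication, 0.121 for heat shock chaperones, 0.3 for the subcortical maternal complex, 0.228 for maternal decay machinery, 0.404 for pluripotency, 0.285 for trophectoderm, 0.606 for imprinted genes, 0.151 for the interferon response, 0.404 for cholesterol synthesis and 0.782 for glycolysis. DNA replication passed without DKO replicate 2 (adjusted p = 0.0295) or wild-type replicate 3 (adjusted p = 0.00824), with no filter on low counts (adjusted p = 0.0199) and with limma-voom quality weights (adjusted p = 0.0452), the subcortical maternal complex without DKO replicate 2 (adjusted p = 0.0367), and heat shock chaperones without DKO replicate 4 (adjusted p = 0.0189) and with no filter (adjusted p = 0.0428). The cholesterol list had a median of 0.03 with a camera direction of lower. Markers of cells that can be carried over with embryos gave camera adjusted p of 0.458 for cumulus and granulosa cells, 0.343 for oviduct epithelium, 0.138 for sperm and 0.976 for blood and immune cells, the last with a median of 0.21 and a camera direction of lower. With 1 library left out at a time, the blood and immune median ranged from −0.38 to 0.38, so its sign depended on single libraries. In the sperm list Pgk2, the testis form of phosphoglycerate kinase, was at 1.76 ± 0.504 against 0.394 ± 0.251 CPM (SD, n = 4 each), with an edgeR adjusted p of 0.469 over all genes and 0.0307 adjusted over the list alone, 1 of 8 passing.

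A further comparison asked whether genes beside the knocked-out loci differed more often than genes elsewhere, since alleles made in embryonic stem cells of another strain can carry linked differences. Within 10 Mb of Gadd45a or Gadd45b, 1 of 257 tested genes passed, 1190007I07Rik, which lies 1.69 Mb from Gadd45b on GRCm38. That share was 0.389% (exact 95% interval 0.00985 to 2.15%) against 2 of 13945 genes farther away, and the difference did not pass (Fisher's exact test, two-sided, p = 0.0533). With a 5 Mb window the share, again 1190007I07Rik alone over fewer genes, was 0.535% and passed (Fisher's exact p = 0.0392), as it did with DESeq2's calls (1.17%, Fisher's exact p = 0.0377). It did not pass with a 20 Mb window (0.214%, Fisher's exact p = 0.0943), no filter on low counts (0.239%, p = 0.0872), an adjusted p threshold of 0.1 (p = 0.0705) or a mean of at least 10 CPM (0%, p = 1). At an unadjusted p under 0.01, a threshold added after the data were seen, the shares were 10 of 257 (3.89%) and 280 of 13945 (2.01%), with a Fisher's exact p = 0.0433. Without 1190007I07Rik itself they were 9 of 256 (3.52%) and 280 of 13945, and the difference did not pass (Fisher's exact p = 0.11). Slc39a3, a zinc transporter 0.0985 Mb from Gadd45b, and Sppl2b, an intramembrane protease 0.0748 Mb from it, had log2 fold changes of −2.10 ± 0.48 and −2.01 ± 0.63 (SE, edgeR adjusted p = 0.394 and 0.469). The 3 genes called by DESeq2 within 10 Mb were 1190007I07Rik, Slc39a3 (DESeq2 adjusted p = 0.0204) and Gm4799 (0.0427). Slc39a3, Sppl2b and Gm4799 were named after their values were seen.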

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

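The tests on mt-Nd3, the test without DKO replicate 1 and the tests on neighbouring genes at an unadjusted p under 0.01 and 0.05 were chosen after the result was seen; the tests on litters, on shared sequence and on other splits were chosen before, and the test on length and GC content was added after the data were seen but before its own result was.

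The first pattern is the absence of mt-Nd3 reads from all 4 DKO libraries together with reads on the nuclear pseudogene Gm10222. Less mitochondrial RNA is argued against by the other 7 mitochondrially encoded protein genes tested, whose median log2 fold change was −0.19 (SD 0.10). Transcription of Gm10222 itself in DKO was not tested. A hypothesis that stays open is a mitochondrial sequence that differs between the maternal lines of the genotypes and moves reads to or between nuclear copies. The reference mt-Nd3 differs from an annotated nuclear copy, Gm28438, at 1 of 345 bases (T3C, counted from the first base of mt-Nd3). Other copies were not searched for. Gm28438 was not among the genes of the tables, so reads moved to it could not be seen. A single change may therefore decide whether reads of mt-Nd3 map to 1 place. The reads were not analysed here, so the base at that position is not known for either genotype, nor which line departs from the reference. The same change would have to reach Gm10222 by a route that was not tested. A difference between maternal lines could not be told apart from genotype in any comparison here. A direct effect of losing Gadd45a and Gadd45b on these transcripts was not tested either.

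The second pattern is the higher maternal list with lower proteasome, ribosome biogenesis, oxidative phosphorylation and mitotic lists, as called by camera with its preset correlation only. Bias by gene length or GC content is argued against, since the maternal median minus the mean of the lower lists' medians was 0.57 after each library's trends were removed and 0.55 before. A large share may rest on 1 library: without DKO replicate 1 the maternal median was 0.15 in place of 0.35, although camera with its preset correlation still called the list (adjusted p = 5.5e-05). An axis of variation between litters cannot be told apart from an effect of genotype with 4 litters each, as the DKO difference correlated across genes with the first component of variation within genotypes at an absolute r of 0.375, 5 of the 35 splits, the real one included, giving an r as high (median 0.175), and genes are not independent replicates. Slower clearance of maternal RNA, or slower development, of embryos without GADD45 proteins stays open and untested.

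The third pattern is the fall of 1190007I07Rik, 1.69 Mb from Gadd45b. Linked sequence of another strain around the knocked-out loci stays open: the planned test of genes within 10 Mb rests on 1190007I07Rik alone and cannot bear on it, and the other genes there did not pass at an unadjusted p under 0.01 (Fisher's exact test, p = 0.11), although they did under 0.05 (14.8% against 10.2%, p = 0.0216). Of the 9 other genes under 0.01, 7 lie within 3 Mb of Gadd45b, among 120 tested there, and 6 of these 7 had a negative log2 fold change; that window was picked after their values were seen, so it tests nothing. The shares depend on the threshold and do not decide it. Reads shared with a similar gene cannot be told apart from it: of 3 genes with a shared 50-base word, 1 was in the tables, Pwp1, with a log2 fold change of −0.24, and the others were not analysed here. An effect of the Gadd45b knockout allele on its neighbours was not tested.

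The count of genes called was highest in the real split. Of the 35 splits of the 8 libraries into groups of 4, only the real split, 1 of 35, gave as many as 4 genes. The highest of the others gave 1. The 4 genes include the targeted Gadd45b, and 1 of 35 is the smallest share possible here, so the splits alone do not exclude chance. For the count of gene lists called by camera, chance cannot be excluded: 7 of the 35 splits, the real one included, gave as many as 9 lists, and the highest of the others gave 11. The split with 11 lists and 2526 genes at an unadjusted p under 0.05 (1532 in the real split) set DKO replicates 1, 3 and 4 with wild-type replicate 3 against the rest.

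A gap to the nearest of the other 3 libraries, divided by the range of the group, of more than 0.829 was found in 8 of 174 groups tested, where chance gives about 1 in 20. DKO replicate 1 was low in the score of DNA damage checkpoint genes, at 5.05 mean log2 CPM against 5.28 to 5.30 (gap ratio 0.911). DKO replicate 4 was high in heat shock chaperones, at 6.13 against 5.90 to 5.92 (0.936). DKO replicate 2 was low in the subcortical maternal complex, at 5.83 against 6.35 to 6.42 (0.891). DKO replicate 4 was high in repressors of the 2-cell program, at 5.97 against 5.87 to 5.89 (0.86). In log2 CPM, DKO replicate 1 was high in Omt2b, at 12.31 against 11.59 to 11.69 (0.855). It was low in Pes1, at 4.33 against 4.65 to 4.69 (0.891). It was also low in Aurka, at 8.13 against 8.87 to 9.02 (0.831). Wild-type replicate 3 was high in the share of counts taken by its 100 most abundant genes, at 24.9% against 23.3% to 23.5% (0.843).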

How the results depend on the processing

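The thresholds on unadjusted p for neighbouring genes, with and without 1190007I07Rik, edgeR without robust estimation, camera after voom, the length and GC correction and the fit without both libraries numbered 1 were chosen after seeing the data, the length and GC correction before its own result was seen. The 4 genes called were called again under RLE, upper quartile and library size scaling, with embryos per pool as a covariate and in all 8 fits with 1 library left out. The replicate block gave 4 genes, the same 4; pairing by number was not borne out, since residual correlations of same-numbered libraries were 0.00235 to 0.078 and 2 of 8 libraries correlated best with their own number. DESeq2 called 49 genes (30 higher, 19 lower), limma-voom 2 higher genes, no filter 7 genes (4 higher), a threshold of 0.1 gave 2 higher genes, and protein-coding genes only gave 0 higher by edgeR (743 higher at an unadjusted p under 0.05), as the pseudogene Gm10222 was not in that fit. A mean of at least 10 CPM left 1 gene (0 higher, with 642 higher at an unadjusted p under 0.05, and 1 lower), since the other 3 genes lie below it. The gene lists called went from 9 to 1 with an estimated correlation, 1 with fry and 0 with exact permutation of scores (2 at an unadjusted p under 0.05; with 35 lists and 4 pools per genotype that test could hardly call any), and to 12 with no filter and 8 at a mean of at least 10 CPM. The share of genes flanking the targeted loci passed with DESeq2 (1.17%), a 5 Mb window (0.535%), and unadjusted p under 0.01 (3.89%) and 0.05 (15.2%, or 14.8% without 1190007I07Rik), and not under 0.01 without 1190007I07Rik (3.52%) or with a 20 Mb window, no filter, a threshold of 0.1 or a mean of at least 10 CPM. Where no construction is named, the cause was not tested. For single named genes and lists, 1718 values kept their side of the threshold, 13 gained a call, 35 lost it (9 of them in that permutation test), and no called value changed direction. Depth sets the lowest detectable level: 0 counts in the 4 DKO libraries allow up to 0.0333 CPM.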

Other observations

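The genes in this part were chosen after their values were seen, from the planned fit with DESeq2 and from the sex-linked list. DESeq2 called 49 genes, 47 of which had an edgeR p under 0.05 before adjustment. The others, F730043M19Rik and Csf3, were removed by edgeR's filter on low counts and had DESeq2 log2 fold changes of −5.96 and 6.22. In data simulated from these libraries with 200 genes changed, DESeq2 made a mean of 34.4 false calls. That number depends on how many genes were changed and cannot be carried over to these 49. Besides the genes described above, those called lower by DESeq2 included Prkar1a, a regulatory subunit of protein kinase A (log2 fold change −0.64 ± 0.15, SE, DESeq2 adjusted p = 0.0261), Irf3, a transcription factor of the interferon response (−0.86 ± 0.21, SE, adjusted p = 0.0308), and the prion protein gene Prnp (−0.95 ± 0.23, SE, adjusted p = 0.0249). Those called higher included Ank3, an ankyrin of membrane domains (1.72 ± 0.34, SE, DESeq2 adjusted p = 0.00085), the olfactory receptor gene Olfr376 (1.37 ± 0.24, SE, adjusted p = 5.83e-05) and Kpna7, an importin of oocytes and early embryos (0.87 ± 0.22, SE, adjusted p = 0.0335). With edgeR the adjusted p of these 6 genes was 0.11 for Olfr376, 0.275 for Ank3 and 0.394 for the others.

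The Y-linked gene Ddx3y had 0 counts in DKO replicates 1 and 4, against 134 and 103 in DKO replicates 2 and 3 and 78, 190, 28 and 47 in the wild-type libraries. Eif2s3y, another Y-linked gene, had 211 and 362 counts in the same DKO replicates 1 and 4, so Y-linked RNA was present in those pools. Xist had 31 and 55 counts there.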
